A study of Homo sapiens with 2 samples.

How the data were processed

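Total RNA of ISL-treated and control cells of each line was hybridised together on a 2-colour Agilent SurePrint human gene expression array, 1 array for LNCaP and 1 for PC-3, both on the same slide. Per the file headers, the slide was scanned and quantified with Agilent Feature Extraction 11.5.1.1. The deposited scanner tables hold, for each spot, the median intensity and the median local background intensity of the green and red channels, without any correction by the authors. They also hold intensities that Feature Extraction had background-subtracted, detrended over the slide and dye-normalized by linear and lowess steps, and as deposited the log10 ratio, which Feature Extraction made from the processed red over the processed green intensity, per the file headers. Flags for spots that are saturated, uneven, or well above background are deposited as well. The deposited value table of the series holds a log2 ratio per probe. It was set against the log10 ratios of the same arrays, converted to log2: 100% of the shared values lay within 0.01, so the scale is log2 and the direction ISL over control. Its column medians were 0.067 for LNCaP and -0.0025 for PC-3, so no further centring was found. It gives values for 58.0% and 54.4% of its probes, all of them well above background in both channels. The filter that left the other probes empty is not given in the sources used here.

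Median intensities were used because the tables hold no mean intensities, although mean intensities had been planned. They were background-corrected with the normexp method of limma 3.58.1 (R 4.3.3) with an offset of 50, and normalized within each array by loess, with control spots and spots marked as outliers given no weight. Of 58717 gene spots, 530 in LNCaP and 669 in PC-3 were marked uneven or outlying and left out, and 0 were saturated. Spots of a probe were averaged. Probes were named by matching their RefSeq transcripts, without versions, to the gene table of assembly GRCh38.p14. This matched 28174 of 50599 probes to 20503 genes, and the other 22425 probes were left unnamed and out of the gene counts. The array grid uses another genome build, so no coordinates are given. A gene's log2 ratio was the median over its probes that were well above background in both channels. Where several probes were measured, their range had a median of 0.26 log2 units on both arrays, and the probes disagreed in sign for 32.5% of such genes in LNCaP and 38.9% in PC-3. Of the genes with several probes and a 2-fold median, all probes had the same sign for 192 of 195 in LNCaP and 12 of 12 in PC-3.

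Genes well above background in a single channel were given as bounds. The brighter channel was divided by the higher of the dim probe's own signal and the lowest signal among probes well above background in the dim channel. These bounds stay open to dye bias, since dyes were not swapped. The lowest such log2 signal of the control channels was 5.76 in LNCaP and 7.18 in PC-3, so bounds between the controls are given with the higher of both lines. For the control channels, signals after loess were brought to a common scale with Aquantile normalization, and a gene needed a probe well above background in both. With 1 array per line no test was run. Genes were counted at a 2-fold difference. The 38 gene lists were written before the data were examined, as were the other settings tried and the rule for naming genes. A list with at least 5 measured members was described by its median and by the percentile of that median among 10000 random lists of the same size, matched on mean signal in 20 bins. A list outside the middle 95% was said to stand apart, which describes these arrays and is no test over replicates. The number outside by chance holds for genes that vary independently. Members of a list can vary together and some lists share genes, so more lists could lie outside by chance.

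The genes named were the 10 highest and 10 lowest on each array, the 10 largest differences each way between lines and between controls, and the 10 genes highest or lowest in both lines. They needed a mean signal at or above the median, an approved-style symbol and probes of the same sign. Added to these were the 2 highest and 2 lowest members of each list that stood apart on an array, 22 genes fixed beforehand and the 5 largest bounds each way per array. XIST and Y-linked genes were not named. A few genes and lists are included in the counts but are not reported here. The alternatives were Agilent's processed signals, no background correction, an offset of 0, median centring, looser and stricter filters on dim probes, the brightest probe of a gene, the submitters' value table and a 1.5-fold threshold. The processing was tested on simulated arrays made from the real signals, with 200 genes changed per array and an intensity-dependent dye effect. Noise between simulated spots had an SD of 0.07 log2 units, and the changes were balanced upwards and downwards. For LNCaP (15105 genes) the estimated log2 ratio had a median of 1.53 for 3-fold genes, whose true value is 1.58, and 67 of 67 passed 2-fold. For PC-3 (14819 genes) it was 1.59, with 67 of 67. For genes changed 1.5-fold, 0 passed on either array, as did 0 of the unchanged genes. Unchanged genes differed between channels only by the simulated noise and dye effect, so these counts give no error rate for the real arrays. Of 400 random gene lists on each simulated array, 5.75% in LNCaP and 4.75% in PC-3 lay outside the middle 95%. Random lists ranked among random lists give such shares by construction. They give no rate for real lists, whose members can vary together. Further tools were Python 3, numpy, pandas and matplotlib.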

Results

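Gene expression was measured in LNCaP and PC-3, established human prostate cancer cell lines, after exposure to isoliquiritigenin (ISL), a chalcone-type flavonoid of licorice root. LNCaP is androgen-sensitive, whereas PC-3 is androgen-independent. Cells were left to attach for 24 h and were then treated for 48 h with 25 µM ISL or with 0.025% DMSO as the vehicle. The treatment protocol names the DMSO control, while the sample characteristics call the control untreated. Each line was measured on 1 array, with ISL-treated RNA in Cy5 (red) and control RNA in Cy3 (green), and no dye swap is labelled. There were therefore no replicates, and every value below describes 1 array without an error over cultures. No test or p-value is given for any gene or list. The number of arrays limits the precision. The arrays held 50599 gene probes, and the control channel was well above background at 64.0% of gene spots in LNCaP and 58.5% in PC-3. The corresponding shares of the ISL channel were 61.3% and 62.0%. Probes printed 10 times gave a median technical SD of 0.04 log2 units in LNCaP and 0.07 in PC-3, which covers the spots of a single array only. Values are log2 ratios of ISL over control unless stated otherwise, and a gene was counted as higher or lower at a 2-fold difference.

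The control channels were first set against each other to describe the lines before treatment, since both carried the same dye. Control LNCaP cells had far higher signals for prostate luminal genes, and control PC-3 cells for basal, mesenchymal and matrix genes. KLK3, which encodes prostate-specific antigen, was well above background only in LNCaP and was at least 295-fold higher there. By the same bound KLK2 was at least 56.6-fold higher in LNCaP and KLK4 at least 234-fold. Among genes measured in both controls, the largest log2 differences towards LNCaP under the naming rule included FOLH1, which encodes prostate-specific membrane antigen (7.58), LRRC26 (6.34), SPON2 (6.31), MAGEA12 (6.05) and MAGEA6 (5.84). SYCE3 (5.70), ACKR3 (5.53), SYNE4 (5.15) and SLC4A4 (5.12) came next. TMPRSS2 was 4.12 higher in LNCaP. The 10 largest towards PC-3 under the naming rule were TIMP1 (-8.14), MSMP (-8.08), APOBEC3C (-7.22), the receptor tyrosine kinase gene MET (-7.15), PI3 (-7.07), GSTP1 (-7.00), PLAT (-6.84), ANXA1 (-6.26), S100A16 (-6.24) and BASP1 (-6.15). DKK1, at least 252-fold, PHACTR3, at least 220-fold, and CAV1, at least 176-fold higher, were measured only in PC-3. STAT3, which is known to be deleted in PC-3, was higher in LNCaP by 3.94 or more, since the PC-3 signal cannot be its transcript if the gene is deleted.

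In all, 13970 genes were measured in both controls, of which 2062 were at least 2-fold higher in LNCaP and 1864 in PC-3. The prostate luminal list had a median difference of 1.87 towards LNCaP (12 genes measured) and the epithelial junction list 1.75, with 21 of 21 members above 0. The basal and mesenchymal list lay at -2.98 (19), the extracellular matrix and invasion list at -2.36 (38), the TGF-beta list at -1.84 (18), the immediate early list at -1.12 (34) and the NF-kB list at -0.82 (23). Smaller shifts outside the middle 95% of random lists were seen for the p53 target list (0.62), the G1/S list (0.44), the ATF4 list (0.38) and the cytosolic ribosomal proteins (0.34). The estrogen responsive (-0.59), interferon (-0.33), ER chaperone (-0.28) and autophagy and lysosome (-0.26) lists lay on the PC-3 side. Together 17 of 37 lists stood apart, where 1.85 would be outside by chance if genes varied independently.

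**Figure D1:**
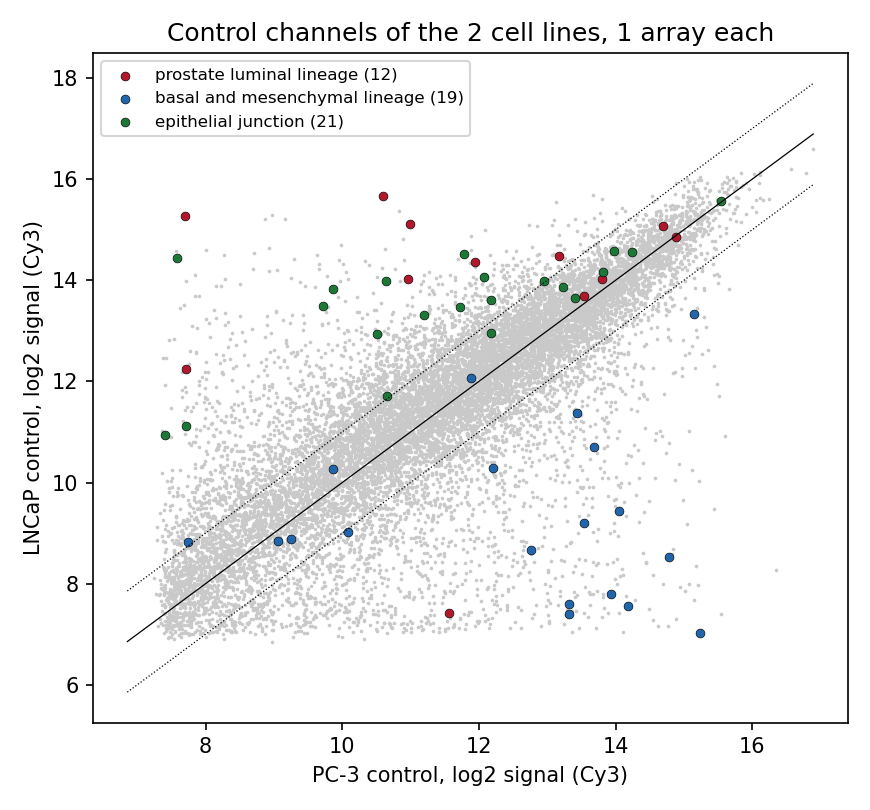
Log2 signals of the control (Cy3) channels, PC-3 on the horizontal and LNCaP on the vertical axis, with 1 point per gene measured in both, the solid line at equal signals and dotted lines at 2-fold differences. Coloured points mark 3 gene lists: luminal genes lie mostly above the line (median difference 1.87) and basal and mesenchymal genes mostly below it (median difference -2.98).

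The main comparison in LNCaP asked which genes differ after exposure to ISL. Genes of cell division and most measured genes of the prostate luminal lineage were lower with ISL, and genes of the NRF2 antioxidant programme were higher. Of 15105 measured genes, 288 were at least 2-fold higher and 833 at least 2-fold lower. The 10 highest genes under the naming rule were AKR1C8 (5.43), AKR1C1 (4.83), AKR1C3 (4.61), the heme oxygenase gene HMOX1 (3.75), the ferritin heavy chain gene FTH1 (3.30), FTHL17 (3.06), the carbonyl reductase gene CBR3 (3.03), PTGR1 (2.96), the thioredoxin reductase gene TXNRD1 (2.64) and the malic enzyme gene ME1 (2.42). The AKR1C and ferritin heavy chain probes target near-identical family members, so the signal of a single member is uncertain. The 10 lowest under the naming rule were APOBEC3B (-3.59), PCLAF (-3.58), PBK (-3.58), KLK3 (-3.57), the mitotic kinesin gene KIF2C (-3.48), MELK (-3.45), the cyclin-dependent kinase gene CDK1 (-3.44), the recombination gene RAD54L (-3.42), BIRC5, which encodes survivin (-3.34), and the kinetochore gene NUF2 (-3.29).

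Mitotic genes were lower almost without exception in LNCaP. All 74 measured members of the G2/M and mitosis list lay below 0 and 71 were at least 2-fold lower, with a median of -2.77 and quartiles of -3.21 and -2.35. The topoisomerase gene TOP2A (-4.69) and CDCA3 (-3.90) were the lowest members, and BUB3 (-0.77) and NCAPH (-0.02) the highest. The cyclin gene CCNB1 was at -2.58, the proliferation marker MKI67 at -2.38 and the mitotic transcription factor gene FOXM1 at -1.82. In the G1/S and DNA replication list 46 of 68 members were at least 2-fold lower (median -1.61). CDC45 (-4.04), needed to start replication forks, and the histone chaperone gene ASF1B (-3.72) were lowest, CASP8AP2 (-0.05) and CDC6 (0.02) were highest, and the helicase subunit gene MCM2 was at -2.00. Both list medians lay below all 10000 random lists matched on expression. CDKN1A, which encodes the CDK inhibitor p21, was higher at 2.11.

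Most measured genes of the prostate luminal and neuroendocrine lists were also lower in LNCaP. The prostate luminal list had a median of -1.12, with 9 of 17 members at least 2-fold lower and 13 below 0. KLK2 (-3.58) and KLK3 (-3.57), which encode secreted proteases of the prostate, were its lowest members, and KRT8 (0.49) and STEAP2 (0.47) its highest. TMPRSS2, a membrane protease gene, was at -1.44 and FKBP5 at -0.76. Of the 22 neuroendocrine genes only 6 were measured, and all 6 were below 0 (median -1.13), from SYT4 (-3.13) and DDC (-1.34) to VGF (-0.70) and UCHL1 (-0.21). With only a single channel well above background, the observed ratios were 1.59-fold higher for SCG2 and 1.44-fold lower for SYT1. The percentile of the neuroendocrine list among random lists was 0.08, and that of the luminal list was 0.

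Targets of NRF2, the transcription factor of the response to oxidants and electrophiles, were higher with ISL in LNCaP. The list had a median of 1.86, 34 of 35 measured members lay above 0 and 28 were at least 2-fold higher. AKR1C1 (4.83) and AKR1C3 (4.61) were the highest members and GSR (0.37) and LRP8 (-0.22) the lowest. The quinone reductase gene NQO1 was at 2.30 and the cystine transporter gene SLC7A11 at 2.36. Without members of near-identical families, 29 genes remained with a median of 1.78. The metallothionein list had a median of 0.71, led by MT1L (1.26) and MT1B (1.07), with MT1F at 0.06 and MT3 at -0.69. The MT1 genes among them are near-identical. The AhR target list lay at 0.40 (9 genes), where NQO1 (2.30) and TIPARP (0.85) were highest and the cytochrome P450 genes CYP1A1 (-0.03) and CYP1A2 (0.02) lowest. Its median was 0.07 without a filter on dim probes, which no longer stood apart. CYP1B1 was not well above background in LNCaP.

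Other stress and biosynthesis lists had smaller shifts upwards in LNCaP. The ER chaperone list had a median of 0.36, from SEC24D (1.18) and DNAJB9 (1.11) to ERO1B (-0.39) and PDIA6 (-0.52). The ATF4 and amino acid response list lay at 0.24, with SLC7A11 (2.36) and DDIT3 (1.51) highest and JDP2 (-0.83) and TXNIP (-1.52) lowest, and TRIB3 was at 0.60. Of the p53 target list (median 0.31), 2 of 34 genes were at least 2-fold higher, namely the stress cytokine gene GDF15 (2.23) and CDKN1A (2.11). PLK2 (-0.57) and SESN1 (-0.91) were its lowest members and GADD45A was at -0.04. The histone list, of core and linker histone genes, had a median of 0.38, where H2AC21 (1.12) and the linker histone gene H1-2 (1.08) were highest and H4C2 (-1.75) and H4C3 (-2.11) lowest. The cholesterol synthesis list lay at 0.32, with LPIN1 (1.39) and SC5D (0.98) highest, EBP (-0.47) and TMEM97 (-0.71) lowest, HMGCS1 at 0.24 and SQLE at -0.31. The autophagy and lysosome list lay at 0.22, with the autophagy receptor gene SQSTM1 (1.79) and the cathepsin gene CTSD (1.46) highest and HEXA (-0.28) and GAA (-0.59) lowest. The heat shock list had a median of 0.18, from HSPB8 (1.77) and CLU (1.64) to SERPINH1 (-0.81) and CHAC2 (-0.89). With Agilent's processed signals the heat shock list was at 0.19 and no longer stood apart.

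Interferon genes were lower in LNCaP, and lists of translation genes had small shifts downwards. The interferon list had a median of -0.43, and 15 of 48 members were at least 2-fold lower, including IFITM1 (-2.44) and IFIT1 (-2.16), while GBP2 (1.11) and PSMB9 (0.28) were highest. The ribosome biogenesis and MYC list lay at -0.31, with MYC itself lowest (-1.62), followed by POLR1E (-1.02), and with RRP12 (0.42) and DDX10 (0.38) highest. The cytosolic ribosomal proteins had a median of -0.26, with 59 of 76 members below 0 and 0 at least 2-fold lower, from RPS2 (-0.85) and RPS29 (-0.73) to RPL37 (0.47) and RPS15 (0.59). This list's median was -0.02 with median centring in place of loess, still below random lists of equally bright genes (percentile 0). The estrogen responsive list lay at -0.32, with the trefoil factor genes TFF3 (-2.60) and TFF1 (-1.80) lowest and PDZK1 (0.61) and STC2 (0.40) highest. The NF-kB and cytokine list lay at -0.24, from IL32 (-2.46) and TNFAIP2 (-2.07) to IL11 (0.87) and LCN2 (2.47). The NF-kB list no longer stood apart with Agilent's processed signals (-0.19), and the estrogen list no longer did among the brighter part of the genes (-0.29).

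The remaining LNCaP lists lay within the middle 95% of random lists. Their medians were 0.17 for the proteasome, 0.15 for androgen and steroid synthesis, 0.14 for TGF-beta targets, 0.12 for hypoxia and glycolysis, 0.12 for immune cell genes, 0.08 for apoptosis regulators, 0.01 for immediate early genes and 0.00 for fatty acid synthesis. Below 0 were the housekeeping list (-0.02), the epithelial junction list (-0.04), oxidative phosphorylation (-0.04), fibroblast and endothelial genes (-0.04), retinoid and xenobiotic metabolism (-0.05), CDK inhibitors and senescence (-0.06), extracellular matrix and invasion (-0.09), PI3K, AKT, mTOR and FOXO (-0.11) and the basal and mesenchymal list (-0.14). In all, 10 lists stood apart upwards and 11 downwards of 38, where 1.90 would be outside by chance if genes varied independently. A further 170 genes were well above background only with ISL and 669 only in the control. Most were dim: by their bounds 25 of the 170 were at least 2-fold higher and 64 of the 669 at least 2-fold lower. Largest by bound, TMEM92 was 5.45-fold higher, KRTAP4-4 4.26-fold, TF 3.95-fold, OR10A7 3.75-fold and CD40LG 3.64-fold. CD40LG had a control signal at the bottom of the measured range. The others are observed ratios to a control signal not well above background. E2F8, a cell cycle transcription factor gene, was 10.6-fold lower and CXCL11 9.38-fold. PLA2G5 was 8.88-fold, the centriole kinase gene PLK4 5.09-fold and ABCC6P1 4.98-fold lower. These too are observed ratios, with ISL signals not well above background. With Agilent's processed signals the LNCaP counts were 541 higher and 925 lower, so that the higher genes made up 36.9% in place of 25.7%.

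In PC-3 the same exposure was accompanied by far fewer 2-fold differences. Of 14819 measured genes, 94 were at least 2-fold higher and 45 at least 2-fold lower. The 10 highest genes under the naming rule were the hair keratin genes KRT81 (2.51) and KRT83 (2.23), the ribosomal RNA gene RNA5-8SN5 (2.37), S100P (1.99), AKR1C8 (1.72), FTHL17 (1.65), the small noncoding RNA genes SNAR-G2 (1.61), SNAR-B2 (1.59) and SNAR-D (1.55), and FTH1 (1.51). The keratin, AKR1C, ferritin and SNAR probes belong to families of near-identical genes. The 10 lowest under the naming rule were the chemokine gene CCL2 (-1.74), the signal recognition particle RNA gene RN7SL1 (-1.52), the interferon-inducible gene BST2 (-1.41), MOXD1 (-1.25), the prostaglandin dehydrogenase gene HPGD (-1.22), TSPAN8 (-1.19), SHISA2 (-1.14), INAVA (-1.14), PRSS35 (-1.12) and the integrin gene ITGAV (-1.07). The balance of higher and lower genes depended on scaling. It was 67.6% higher with loess, 93.5% with median centring (303 higher, 21 lower) and 48.4% with Agilent's processed signals (121 higher, 129 lower).

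Histone and NRF2 target genes led the lists that were higher in PC-3. The histone list had a median of 0.49, with 41 of 48 members above 0, H2AC21 (1.06) and H2AC7 (0.99) highest and H4C2 (-0.17) and H4C11 (-0.17) lowest. The NRF2 list had a median of 0.43, with 34 of 36 members above 0 and 9 at least 2-fold higher. The aldo-keto reductase genes AKR1B10 (1.70) and AKR1B1 (1.61) were highest and SRXN1 (-0.01) and IDH1 (-0.12) lowest, while HMOX1 was at 1.37 and NQO1 at 0.75. Without near-identical families the NRF2 median was 0.41 over 31 genes. The ATF4 list lay at 0.29, with the pseudokinase gene TRIB3 (1.35) and DDIT3 (1.29) highest and KLHL24 (-0.41) and TXNIP (-0.69) lowest. The metallothionein list, which also holds the zinc transporter gene SLC30A1 (0.66), lay at 0.28, from MT1X (0.53) to MT1E (0.11) and MT1M (-0.37). Cytosolic ribosomal proteins lay at 0.22, with 56 of 71 members above 0, RPL19 (0.83) among the highest and RPL9 (-0.23) and RPS12 (-0.29) lowest. The immediate early list lay at 0.20, with KLF4 (1.19) and MAFF (1.01) highest and SPRY4 (-0.61) and EGR1 (-0.76) lowest. Among the brighter part of the genes the ribosomal (0.23) and metallothionein (0.28) lists no longer stood apart.

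Interferon and replication genes were lower in PC-3 by small amounts. The interferon list had a median of -0.29, with 36 of 49 members below 0, BST2 (-1.41) and IFI44 (-1.12) lowest and ISG20 (0.85) and IFIT3 (0.65) highest. FKBP5 was at -0.50 and TMPRSS2 at -0.21. KLK3 and CDKN1A could not be given a ratio in PC-3, because their control signals were not well above background. CDKN1A was well above background there only with ISL and was at least 1.32-fold higher, at signals close to background. The G1/S list had a median of -0.19, with 57 of 73 members below 0 and 0 at least 2-fold lower, from GINS1 (-0.79) and MCM2 (-0.73) to RFC2 (0.53) and ORC6 (0.63). The G2/M list, at -0.10 over 76 genes, lay at percentile 6.93 of random lists and was not counted as apart. Median centring moved the median of all PC-3 genes from -0.02 to 0.15 and that of the G2/M list to 0.05, which then stood apart below random lists (percentile 1.43). CDK1 was at -0.72, MKI67 at -0.28, CCNB1 at -0.22, BIRC5 at -0.03 and FOXM1 at 0.06.

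The other PC-3 lists lay within the middle 95% of random lists. Their medians were 0.18 for immune cell genes, 0.13 for the basal and mesenchymal list, 0.11 for hypoxia and glycolysis, 0.10 for ribosome biogenesis and MYC, 0.03 for oxidative phosphorylation, 0.03 for fatty acid synthesis and 0.00 for autophagy and lysosome. The heat shock list (-0.02), the NF-kB list (-0.02), TGF-beta targets (-0.03), androgen and steroid synthesis (-0.03), the luminal list (-0.05), apoptosis regulators (-0.05) and CDK inhibitors (-0.05) lay close to 0. Medians of -0.06 were found for the ER chaperone and estrogen lists, and -0.08 for p53 targets, cholesterol synthesis, epithelial junction, proteasome and the PI3K, AKT, mTOR and FOXO list. Lower still were housekeeping (-0.09), neuroendocrine (-0.09), fibroblast and endothelial (-0.11), retinoid and xenobiotic metabolism (-0.11), extracellular matrix (-0.13) and AhR targets (-0.18). GADD45A was at 0.36, CYP1A1 at -0.06, CYP1B1 at -0.36, HMGCS1 at -0.32 and SQLE at -0.27. In all, 6 lists stood apart upwards and 3 downwards, against 1.90 by chance if genes varied independently. A further 719 genes were well above background only with ISL and 142 only in the control. Most were dim: by their bounds 4 of the 719 were at least 2-fold higher and 19 of the 142 at least 2-fold lower. KRTAP6-2 was at least 2.70-fold higher, OR56A4 at least 2.41-fold, TAFA4 at least 2.27-fold, PDE2A at least 2.19-fold and PLAAT1 at least 1.97-fold. STAT3 was at least 2.52-fold lower by its 1 measured probe, which for a deleted gene is not a loss of transcript. HSD3B2 was at least 2.40-fold, KIF1A and TNIP3 at least 2.29-fold and TPH2 at least 2.27-fold lower, all at signals close to background.

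**Figure D2:**
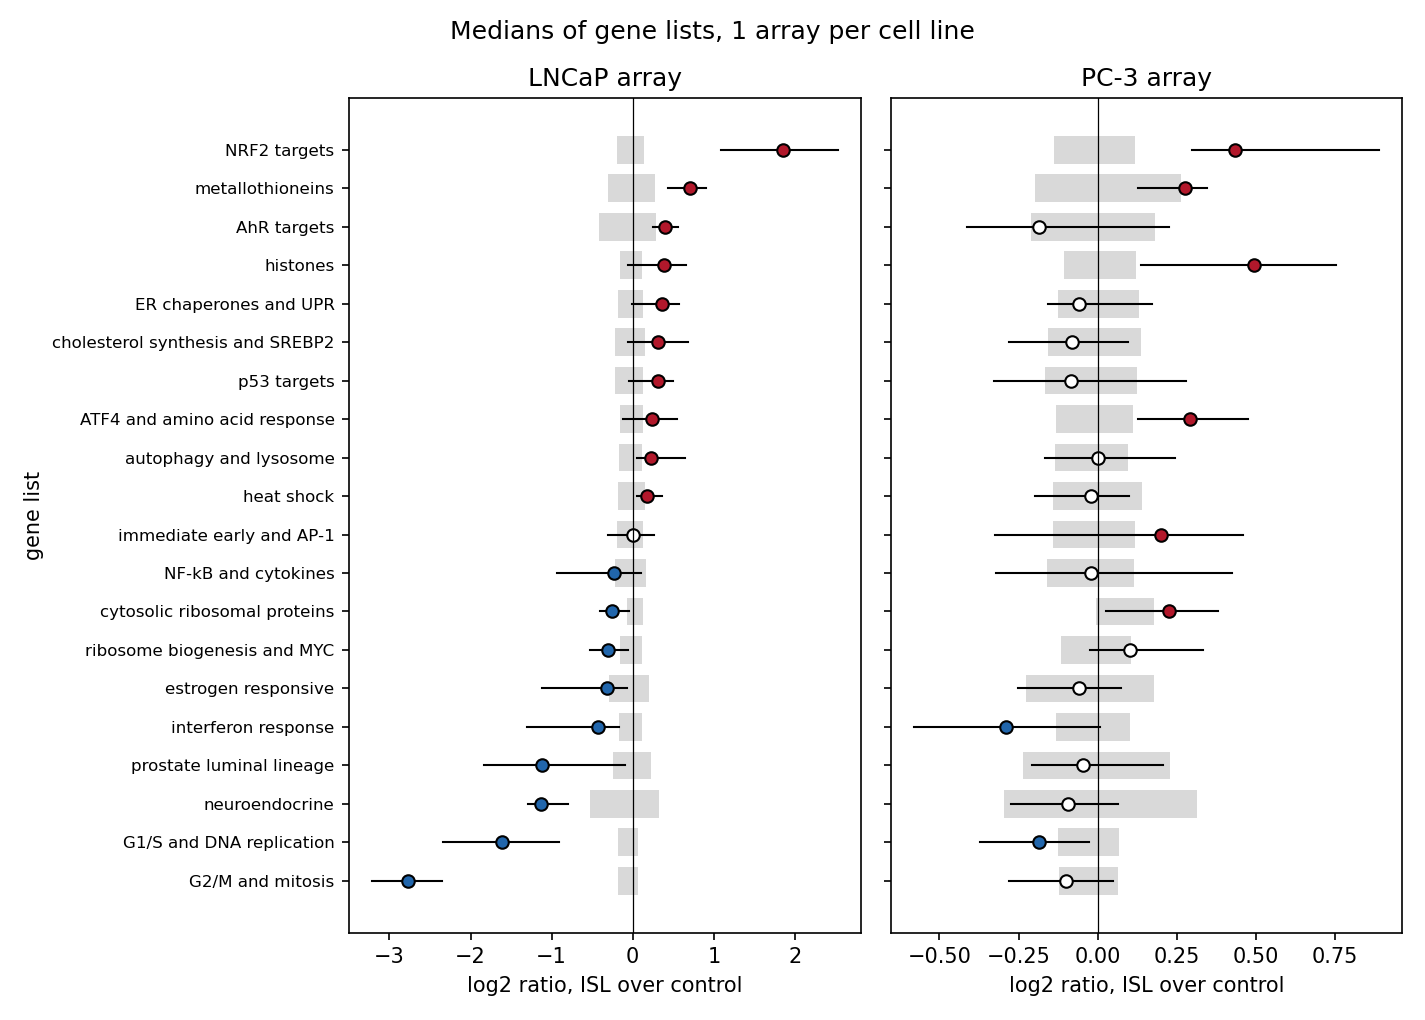
Median log2 ratio (ISL over control, horizontal axis) of gene lists that stood apart on at least 1 array, for LNCaP (left) and PC-3 (right, on a narrower scale), with lines for the quartiles of the members and grey bars for the middle 95% of random lists matched on expression. Red and blue points lie above and below that range and white points within it; the G2/M list reaches -2.77 in LNCaP and -0.10 in PC-3.

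The responses of the lines were then compared over 13664 genes measured on both arrays. NRF2 targets were higher in both (list medians 1.86 in LNCaP and 0.43 in PC-3), and probes of ferritin genes were too. Cell cycle genes were far lower in LNCaP than in PC-3, where the G1/S list (-0.19) was lower by a small amount. Across genes the log2 ratios had a Pearson correlation of 0.20 and a Spearman correlation of 0.18, and genes are not independent replicates. At least 2-fold higher in both lines were 28 genes, where independent lists of these sizes would share 1.44. At least 2-fold lower in both were 9 genes, against 1.29. Under the naming rule, the genes with the highest smaller ratio of the lines were S100P (1.94 in LNCaP, 1.99 in PC-3), AKR1C8 (5.43, 1.72), FTHL17 (3.06, 1.65), FTH1 (3.30, 1.51), GDF15 (2.23, 1.40), HMOX1 (3.75, 1.37), the ferritin light chain gene FTL (1.36, 1.47), DDIT3 (1.51, 1.29), CD68 (1.19, 1.31) and H2AC19 (1.11, 1.11). AKR1B10 (3.62, 1.70), AKR1B1 (3.20, 1.61) and AKR1C1 (4.83, 1.53), dimmer on at least 1 array than the rule asks, were also higher in both. Lowest in both under the naming rule, which asks for bright signals in both lines, were BST2 (-1.82, -1.41), TMSB15A (-3.10, -0.94), the apoptosis inhibitor gene BIRC3 (-0.94, -0.81), GINS1 (-2.42, -0.79), TMEM19 (-0.76, -0.94), MCM2 (-2.00, -0.73), ALDH1A3 (-0.86, -0.72), LPAR6 (-1.29, -0.72), IGF1R (-0.71, -0.68) and ZWINT (-2.04, -0.68). Outside that rule, HPGD (-2.03, -1.22), TSPAN8 (-1.53, -1.19), INAVA (-1.14, -1.14), IFI44 (-1.46, -1.12) and SLC4A4 (-1.27, -1.02) were at least 2-fold lower in both.

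The log2 ratios differed by 2 or more between the lines for 193 genes, of which 22 were higher and 171 lower in LNCaP. Under the naming rule, the largest differences upwards were at AKR1C3 (3.82), AKR1C8 (3.71), CBR3 (2.96), PTGR1 (2.53), HMOX1 (2.39), TXNRD1 (2.35), the tubulin gene TUBB3 (2.32), ME1 (2.16), SLC7A11 (2.07) and ACSL1 (1.95). The largest downwards under the same rule were at RAD54L (-3.37), PTTG2 (-3.32), BIRC5 (-3.31), KIF2C (-3.31), MELK (-3.29), PTTG3P (-3.28), APOBEC3B (-3.24), PTTG1 (-3.16), NDC80 (-3.11) and PBK (-3.08). Among genes dimmer than the rule asks on at least 1 array, CDCA3 (-4.35), TOP2A (-4.11), CDC45 (-4.02) and ASF1B (-3.57) had larger differences downwards, and AKR1C1 differed by 3.29 upwards. The PTTG genes are near-identical copies. The list medians of these differences were -2.60 for G2/M, -1.37 for G1/S, -0.52 for cytosolic ribosomal proteins, -0.43 for ribosome biogenesis and MYC, -0.43 for the luminal list and -0.33 for interferon genes. Upwards they were 1.51 for NRF2 targets, 0.50 for metallothioneins, 0.37 for ER chaperones, 0.37 for cholesterol synthesis, 0.32 for autophagy and lysosome, 0.28 for androgen and steroid synthesis, 0.27 for p53 targets, 0.20 for heat shock and 0.18 for the proteasome. In all, 16 of 37 lists lay outside the middle 95% of random lists, against 1.85 by chance if genes varied independently. Among the brighter part of the genes the luminal (-0.43) and p53 (0.09) lists did not. The steroid synthesis list lost its place under 6 settings, with medians down to 0.07 with median centring. These 6 hold Agilent's processed signals and the submitters' value table, which repeats them and is no separate setting. The proteasome list turned to -0.07 with median centring, though still above random lists (percentile 98.8). The differences themselves were not tested over replicates.

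**Figure D3:**
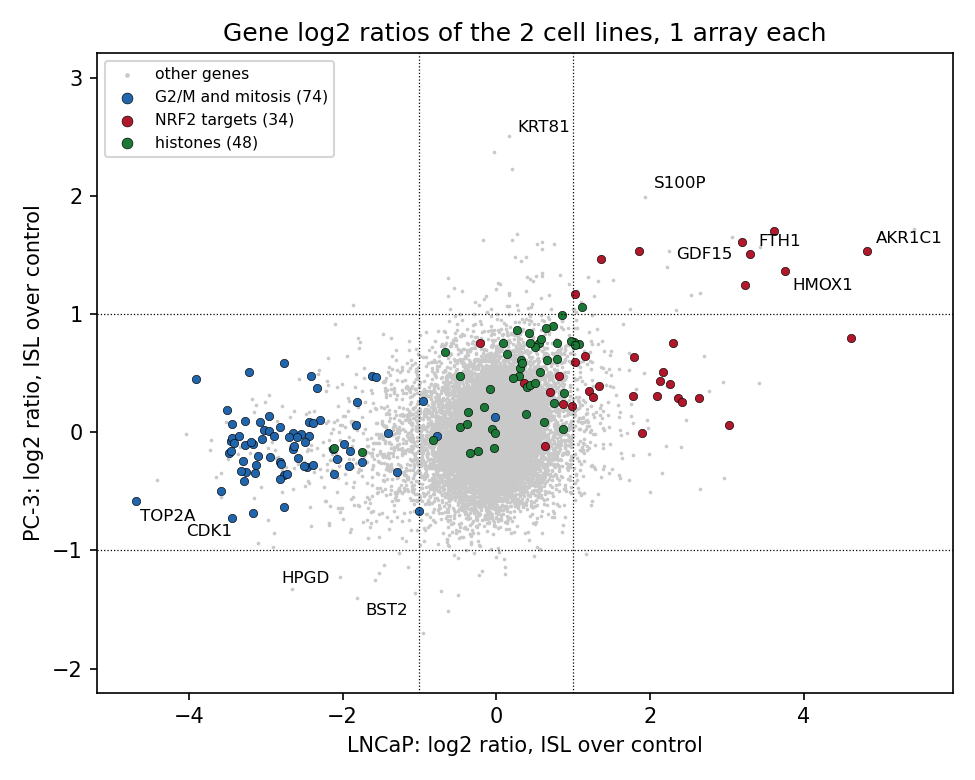
Log2 ratios of ISL over control in LNCaP (horizontal axis) and PC-3 (vertical axis), with 1 point per gene measured on both arrays, dotted lines at 2-fold differences and 3 gene lists in colour. G2/M genes extend to -4.69 in LNCaP (TOP2A) and stay within 1 log2 unit of 0 in PC-3, and the NRF2 targets AKR1C1, FTH1 and HMOX1 lie past 2-fold on both axes.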

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

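The tests on spike-in ratios, on genes measured on both arrays and on matched random lists were chosen after the results they measure had been seen; the others in this part were written before. Cytosolic ribosomal protein genes stood apart on opposite sides in the lines, at -0.26 in LNCaP and 0.22 in PC-3, and this difference was not tested over replicates. These are bright probes, so the normalization could produce such a shift. The LNCaP minus PC-3 median was -0.52. With median centring, which uses no loess, it was -0.77, which argues against loess as the source of the difference. Random lists of equally bright genes then had a median of -0.35, so part of the -0.77 was shared by bright genes. With Agilent's processed signals the list was at -0.46, but these include a lowess step and cannot test loess. The difference of -0.52 had percentile 0 among random lists of equally bright genes, which argues against brightness alone. This is the same percentile by which the list stood apart, so it is no separate evidence. The LNCaP list median itself was -0.02 with median centring, while the list stayed below random lists of equally bright genes (percentile 0). A biological difference between the lines stays open.

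The genes PRR11 and ZNF117 were past 2-fold in opposite directions, and each is measured by 1 probe. PRR11 was at -1.87 in LNCaP and 1.07 in PC-3, and ZNF117 at 1.17 and -1.03. These differences were not tested, and both genes were named after their values were seen. Independent lists of these sizes would give 4.24 genes lower in LNCaP and higher in PC-3 and 0.44 of the opposite kind, where 1 of each was found. Probes without a gene name, which entered no comparison, also passed 2-fold: 442 of 9075 measured in LNCaP (243 higher, 199 lower) and 86 of 7671 in PC-3 (64 higher, 22 lower).

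PC-3 had 139 genes past 2-fold and LNCaP 1121. The gap was smaller with median centring (324 and 1157) and with Agilent's processed signals (250 and 1466). A compressed ratio scale on the PC-3 array could give such a gap. The 10 spike-in transcripts present on both arrays had a slope of 1.02 of PC-3 on LNCaP log2 ratios (0.99 to 1.06 with each left out in turn), where compression would need 0.59 or less. Restricted to the 13664 genes measured on both arrays, LNCaP had 947 such genes and PC-3 107, a ratio of 8.85, so the number of measured genes does not account for the gap. The median SD of repeated spots was smaller in LNCaP than in PC-3 (ratio 0.64), which argues against spot noise on the LNCaP array. A difference in sensitivity between the lines stays open as a hypothesis, and so does a difference between the cultures, since each line has 1 array.

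The overlap of responses, with 28 genes higher and 9 lower in both lines, could come in part from dye bias, because ISL was in Cy5 on both arrays. Bias of single probes would not carry over to other probes of the same gene. Over 3557 genes with several probes, the covariance between arrays of different probes was 0.52 of that of the same probe (interval 0.41 to 0.61 by resampling genes). Below 0.2 had been set for single-probe bias as the cause and above 0.5 for its absence, so probe bias is not the whole source, and how much it adds cannot be told apart from it. Dye bias common to all probes of a transcript stays open without a dye-swapped array.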

How the results depend on the processing

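All named genes past 2-fold (134 values) kept their sign under every alternative that measured them, and 1153 of 1169 alternative values stayed past 2-fold. Among all named genes, also those short of 2-fold, 628 alternative values were classed as moved and 2625 as the same. The alternatives reprocess the same spots and are no independent check. The submitters' value table repeats Agilent's ratios, so the tallies of genes and lists hold that alternative again. The correlation between lines stayed between 0.18 and 0.23. No paired analysis was possible because each line has a single array without replicates. No spot was saturated, so leaving out saturated spots gave no values. Of the list medians, 399 kept their place among random lists, 20 no longer stood apart, 1 newly did (G2/M in PC-3, below random lists with median centring), and the proteasome difference between lines turned to -0.073 with median centring. Counts depended more on the settings. With Agilent's processed signals, and equally with the submitters' value table, 541 genes were higher in LNCaP, 129 lower in PC-3, 16 lower in both lines, and 49 had a ratio at least 2 log2 units higher in LNCaP. Median centring gave 303 higher and 21 lower genes in PC-3, 51 higher and 5 lower in both. An offset of 0 gave 75 lower genes in PC-3, probes above background in at least 1 channel 111, and no filter 108. Limiting the count to the brighter part of the genes left, by its construction, 130 higher and 292 lower in LNCaP, 42 and 13 in PC-3, 12 and 1 in both, and 9 and 59 that differed between lines. The 1.5-fold threshold gave 1124 and 1920 in LNCaP, 697 and 596 in PC-3, 156 and 118 in both, and 187 and 613 that differed. Apart from the threshold and the brighter part, the cause was not tested. In control cells the counts stayed within 1.5 times under all 5 alternatives. Signal over background limits the ratios: 4559 genes in LNCaP and 4823 in PC-3 were not well above it in either channel.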

Other observations

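Of genes annotated as long noncoding RNA, 732 were measured in LNCaP, with 22 at least 2-fold higher and 25 lower, and 665 in PC-3, with 8 higher and 1 lower. The histone genes were not uniform within either line. H4 genes of the list had medians of -0.01 in LNCaP (11 genes) and -0.04 in PC-3 (10 genes), while its other histone genes lay at 0.43 and 0.61 (38 genes in each). TIPARP, a target of the aryl hydrocarbon receptor, was at 0.85 in LNCaP and -0.85 in PC-3, and it was lower in control LNCaP than in control PC-3 (-4.21). The vimentin gene VIM, chosen after its values were seen, was at -2.09 in LNCaP and 0.91 in PC-3.

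Of the tests below, only that on the control level was written before its result was seen. The NRF2 list had a smaller response in PC-3 (0.43) than in LNCaP (1.86). A hypothesis is that these genes were already high in control PC-3 cells. The control difference, LNCaP minus PC-3, had a list median of -0.18, at percentile 4.10 of random lists. This lay within the middle 95%, so the list did not stand apart towards PC-3. By that limit a higher control level in PC-3 was not found as the source for the list as a whole. Members differed: 7 of 34 were at least 2-fold higher in control PC-3, among them AKR1C3 (-3.22) and CBR3 (-2.18). Another 6 were at least 2-fold higher in control LNCaP, among them GSR (1.84). For single members a higher control level in PC-3 stays open. The interval by resampling members, -0.39 to 0.18, covers both signs, so a small difference in control level is not excluded. A related hypothesis is that both lines reach the same level with ISL. The ISL channels differed by a list median of 1.02 towards LNCaP, at percentile 100, so the levels with ISL were not the same. This value follows largely from the control difference and the difference of the ratios (list median 1.51), so it is no separate evidence. A difference in uptake or metabolism of ISL was not tested.

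The cell cycle lists were lower in LNCaP than in PC-3. A hypothesis is a difference in p53 activity, since LNCaP is known to carry functional p53 and PC-3 lacks it. The LNCaP minus PC-3 median of the p53 target list was 0.27, at percentile 99.9, in line with that hypothesis. It was 0.10 with median centring and 0.09 among the brighter part of the genes, where it no longer stood apart, and only 2 of 34 p53 targets were past 2-fold in LNCaP. The list may also respond to stress without p53, as GDF15 was at 1.40 in PC-3. CDKN1A had no ratio in PC-3 and is not part of the difference of 0.27.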
